A study of Mus musculus with 10 samples.

How the data were processed

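RNA from whole ear skin of 10 C57Bl/6 mice was sequenced, with 1 library per mouse. The labels place 4 libraries in the Littermate group and 6 in the Experimental group. Per the series text, both groups received topical MC903 (calipotriol, a vitamin D analogue that induces a skin inflammation with itch) at 1 nM daily for 12 days. Per the labels' protocols, total RNA was depleted of ribosomal RNA by hybridization, fragmented and reverse transcribed from random hexamers, and single reads of 50 bases were sequenced. No strand marking is described, so reads of a gene and of an overlapping antisense gene cannot be told apart. Depletion keeps RNA with no poly(A) tail, such as replication-dependent histone RNA.

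Per the submitters' processing notes, STAR 2.0.4b, Subread and featureCounts 1.4.5 were used with the mm10 genome. The annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. Each deposited file lists 41388 Ensembl genes with their coordinates and lengths. Per the file headers, the first value is the read count per gene as the authors deposited it. The deposited CPM values equal the count divided by the library's total, scaled to counts per 1e6. The deposited RPKM values equal that CPM divided by the gene length in kilobases. Only the counts entered the tests. Gene symbols were matched to 97.3% of the gene identifiers. Coordinates are those of the deposited files (mm10).

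Genes were tested with edgeR 4.0.16 (TMM factors, filterByExpr by group, robust dispersion, quasi-likelihood test, two-sided) on the counts of all 10 libraries, with group as the only term. P-values were adjusted by the Benjamini-Hochberg method over the 16830 genes kept by the filter, at a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Normalized CPM values use the TMM factors, which ran from 0.984 to 1.02, and their errors are SD over libraries. Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes and adjustment over the 40 lists. The lists cover cytokines and receptors, skin cell types, immune cells, other tissues of the ear, signs of RNA handling, and genes within 5 Mb of Il4ra, Jak1 and Scn10a. The symbol pattern for ribosomal proteins also takes in 9 genes of S6 kinases. A few list members went by an older symbol, and 4 matched none. Measures of whole libraries were compared by an exact permutation test over all 210 splits of 10 libraries into 4 and 6. Principal components were taken over the 500 most variable genes on log2 CPM with a prior count of 2. GC content came from the longest transcript of each gene in GENCODE M21, found for 99.3% of the tested genes.

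The gene lists, the tests and the rule for naming genes were fixed before the data were examined. The rule always takes Il4ra, Jak1, Scn10a, Il13ra1 and Il2rg. It then takes, among genes with a mean of at least 1 CPM in a group and a symbol that is no predicted model, the 12 that passed with the largest change in each direction. Where fewer than 5 passed in a direction, it takes the genes with the lowest p up to 10. From each list it takes up to 4 members that passed, filled to 2 by the lowest p. A gene that the rule takes from a list is not reported here.

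Total counts ran from 11520348 to 41935183 per library, so that 3 counts were worth 0.0715 to 0.260 CPM. The common biological coefficient of variation was 12.8%. The steps were tested on simulated counts for this comparison, with 200 genes changed and the other genes of the macrophage and monocyte list raised as a set. Among 16688 genes, edgeR recovered 51 of 98 genes changed by 1.5 times (52.0%) and 78 of 95 changed by 2 times (82.1%). In the same simulation 8 of its 147 calls were false (5.44%), where calls of the raised list genes count as neither recovered nor false.

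The alternatives were other size factors, other filters on low counts, the replicate number as a block, the summed level of the Y-linked genes as a covariate, DESeq2 1.42.0, limma voom with and without sample quality weights, and each library left out in turn. For lists, an estimated correlation and the fry test were added, and for the components other settings. Corrections for GC content and length by a lowess curve per library, and the removal of further libraries, were chosen after seeing the data. The labels give no batch, litter or sex. Whether the mice were housed or treated together is not given in the sources used here.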

Results

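The transcriptome of whole ear skin was measured in 10 mice under topical MC903, a vitamin D analogue that produces an inflammation resembling atopic dermatitis. Total counts lay between 12865459 and 14324433 in the 4 Littermate libraries and between 11520348 and 41935183 in the 6 Experimental libraries. The labels disagree about the Experimental genotype. The series text names a floxed Il4ra gene, which encodes the receptor chain shared by IL-4 and IL-13, whereas the genotype label of each Experimental sample names a floxed Jak1 gene, which encodes a kinase downstream of that receptor. Both name NaV1.8, the sodium channel of pain- and itch-sensing neurons. The 6 libraries are therefore called Experimental, and which of the genes was deleted is not settled here. The comparison asks how the treated skin of these conditional mice differed from that of littermates.

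No difference in either candidate gene was detected in whole skin. Il4ra (ENSMUSG00000030748, mm10 chromosome 7, 125552282 to 125579472) stood at 217 ± 23.5 normalized CPM (SD, n = 4) in Littermates and 189 ± 46.9 (SD, n = 6) in Experimental mice. Its log2 fold change was -0.20 with a 95% interval from -0.55 to 0.16 (edgeR, adjusted p = 0.678). Its values ran from 184 to 236 CPM in Littermates and from 130 to 270 CPM in Experimental libraries. Jak1 (ENSMUSG00000028530, chromosome 4, 101152367 to 101265282) stood at 310 ± 25.4 CPM (SD, n = 4) and 298 ± 18.5 CPM (SD, n = 6), a log2 fold change of -0.06 with an interval from -0.22 to 0.10 (edgeR, adjusted p = 0.815). Scn10a, which encodes NaV1.8, had 2 counts over all 10 libraries and was not tested. The cell bodies of sensory neurons lie outside the ear, so skin RNA is a weak check of a deletion in them. The other chains of the receptors were Il13ra1, at a log2 fold change of 0.20 (edgeR, adjusted p = 0.30), and Il2rg, at 0.22 (edgeR, adjusted p = 0.676). The lists of genes near Il4ra, Jak1 and Scn10a had median log2 fold changes of -0.03, -0.01 and 0.01 and did not pass (camera, adjusted p = 0.465, 0.548 and 0.811). Of the 148 tested genes near Il4ra, 3 passed when adjusted over the list alone, Bag3 at -0.50, Fbrs at -0.42 and Sh2b1 at -0.35, and the list passed fry for changes in either direction (adjusted p = 0.0474). By edgeR, 11.5% of these genes had an unadjusted p under 0.05, against 11.8% of all tested genes. These calls therefore do not set the region apart.

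Of 16830 genes tested, 3 differed between the groups, 1 higher and 2 lower in Experimental skin. Lyz1 (ENSMUSG00000069515, chromosome 10, 117287796 to 117292868), one of the mouse lysozyme genes, rose from 19.0 ± 2.5 CPM (SD, n = 4) to 72.5 ± 13.8 CPM (SD, n = 6), a log2 fold change of 1.93 with an SE of 0.14 (edgeR, adjusted p = 4.3e-05). Its neighbour Lyz2 (ENSMUSG00000069516, chromosome 10, 117277334 to 117282274), the lysozyme of macrophages and neutrophils, fell from 445 ± 65.5 to 237 ± 26.8 CPM, a log2 fold change of -0.91 with an SE of 0.10 (edgeR, adjusted p = 0.0026). Sox9 (ENSMUSG00000000567, chromosome 11, 112782224 to 112787760), a transcription factor of hair follicle stem cells and cartilage, fell from 27.9 ± 1.46 to 16.9 ± 1.57 CPM, a log2 fold change of -0.73 with an SE of 0.09 (edgeR, adjusted p = 0.0033). For each of the 3 genes all 6 Experimental libraries lay outside the range of all 4 Littermates. The lysozyme values are uncertain one against the other, since 16.1% of the 50-base windows of Lyz1 transcripts are identical in Lyz2 and 63.0% lie within 2 mismatches of it. At an unadjusted p under 0.05 there were 1978 genes, 615 higher and 1363 lower, where 841.5 would be expected by chance. Part of the lean to lower genes went with GC content. After GC correction, chosen after seeing the data, there were 1715 such genes, 724 higher and 991 lower. The count of 3 depended on the libraries and the tool: it was 343 without Littermate 2, 28 without Experimental 6, 8 without Littermate 3 and 563 without Littermate 2 and Experimental 6, while DESeq2 called 232, edgeR with no filter 78, edgeR with a block for the replicate number 67 and voom with quality weights 60. Lyz1 and Lyz2 were called in all 24 of the alternative fits. Sox9 was called in 23 and lost its call with the level of the Y-linked genes as a covariate, at a log2 fold change of -0.71 (edgeR, adjusted p = 0.10), where 2 genes were called.

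**Figure D1:**
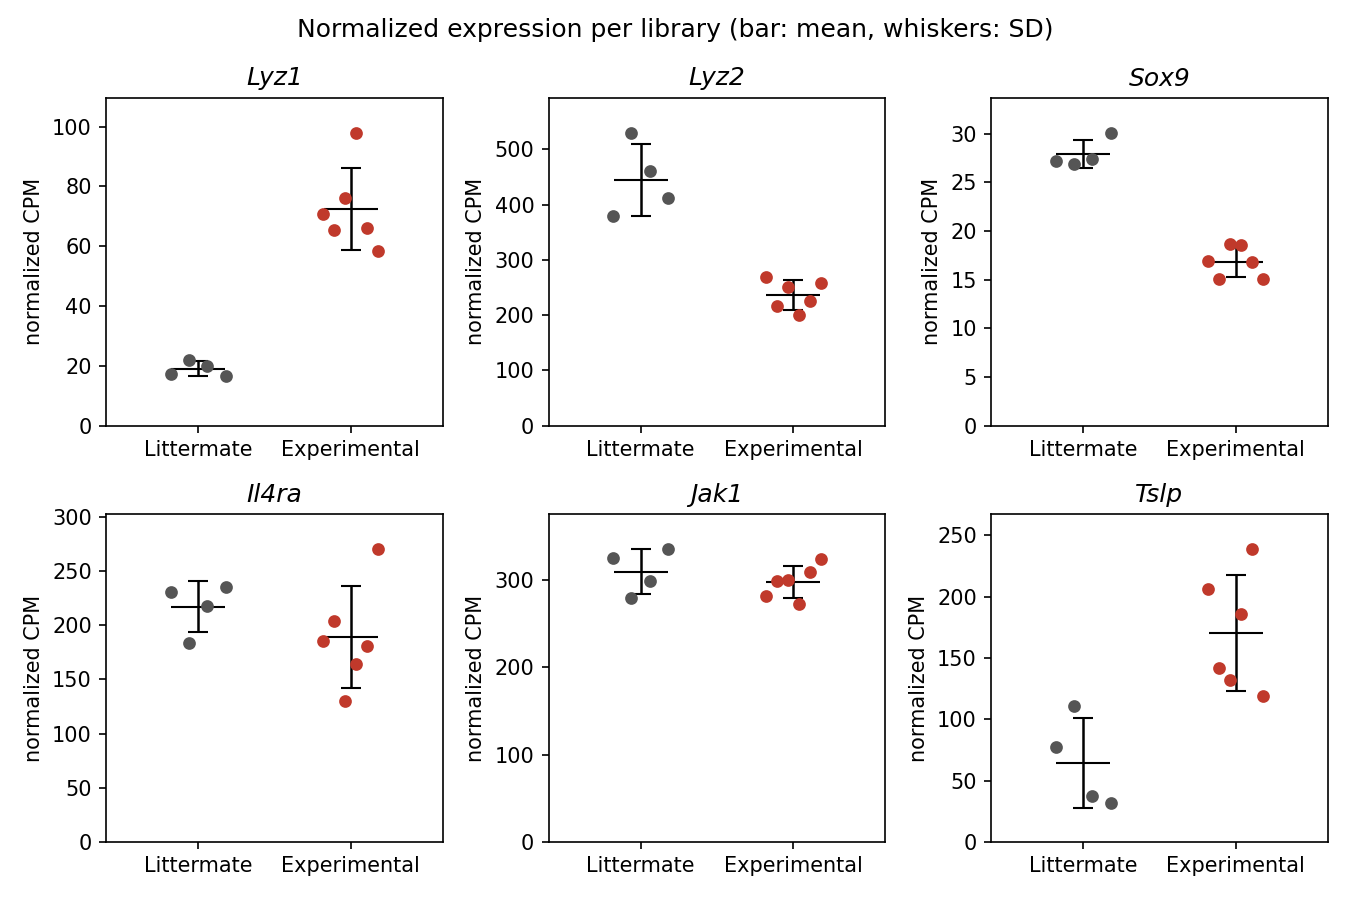
Normalized CPM (y axes, linear from 0) of 6 genes in each library of the Littermate (n = 4) and Experimental (n = 6) groups, with points for libraries, horizontal bars for means and whiskers for SD. Lyz1 averaged 19.0 and 72.5 CPM, Lyz2 445 and 237 CPM and Sox9 27.9 and 16.9 CPM with no overlap of the groups, whereas the values of Il4ra and Jak1 overlapped and Tslp did not pass the test.

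The genes next in rank did not pass and are given as values. On the higher side these were Krtap6-2 and Krtap21-1, keratin-associated proteins of the hair shaft, at log2 fold changes of 1.95 and 1.98 (edgeR, adjusted p = 0.0834 and 0.0839), and Mmp13, a collagenase, at 1.26 (edgeR, adjusted p = 0.0895). Tmem238l stood at 0.75, Mir17hg at 0.43, Slc10a6 at 0.32, Dnase1l2 at 0.40 and Tmem86a at 0.50. On the lower side Cd209d, a lectin of the DC-SIGN family, stood at -0.41 (edgeR, adjusted p = 0.0653), the transcription factor Nfic at -0.77 and the synaptic adhesion gene Nlgn2 at -0.60 (edgeR, adjusted p = 0.0834 for both). Mtss1l, Mbd6, Prr12, Ankrd52 and Synpo2 lay between -0.67 and -0.49. With GC correction, chosen after seeing the data, most of these lower genes shrank. Nfic then stood at -0.66, Nlgn2 at -0.44, Mtss1l at -0.47, Mbd6 at -0.32, Prr12 at -0.49 and Ankrd52 at -0.44. Cd209d and Synpo2 did not shrink, at -0.42 and -0.51. Krtap and Sprr genes belong to families of similar sequence, so their reads may be shared between members.

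The lists of type 2 and type 17 inflammation, the IL-4 and IL-13 response, receptor chains and itch mediators did not pass in the main test, though 3 of these 5 did in at least 1 alternative. Of the 16 tested genes of type 2 inflammation none passed, over all genes or adjusted over the list alone, and the median log2 fold change was 0.10 (camera, adjusted p = 0.471). The member with the lowest p was Tslp, the epithelial cytokine that MC903 induces, at 64.4 ± 37.0 CPM (SD, n = 4) in Littermates and 170 ± 47.2 CPM (SD, n = 6) in Experimental mice. Its log2 fold change of 1.4 did not pass over all genes (edgeR, adjusted p = 0.229), although 6 of 6 Experimental libraries lay above all Littermates. Adjusted over a list alone, Tslp passed among the 7 tested genes of the vitamin D response list (edgeR, adjusted p = 0.0373). It did not pass in the longer lists of type 2 inflammation (0.0852) and itch mediators (0.117). Gata3 stood at -0.32. The IL-4 and IL-13 response list had a median of -0.21 over 14 genes (camera, adjusted p = 0.0611), with Arg1 at -0.52 and Clec10a at -0.21. It passed in 8 of 23 alternatives, among them those without Experimental 6 (camera, adjusted p = 0.0109), without Experimental 2 (0.0240), without Littermate 2 (0.0381) and without Littermate 2 and Experimental 6 (0.0031), and not with an estimated correlation (adjusted p = 0.675). With each library left out its median ran from -0.24 to -0.11. The lists of JAK-STAT and receptor chains (median -0.04, adjusted p = 0.737), itch mediators and nerve growth factors (-0.05, adjusted p = 0.737), vitamin D response (0.11, adjusted p = 0.465) and sensory neurons (-0.00, adjusted p = 0.737) did not pass in the main test. Of these only the JAK-STAT list passed in an alternative, without Littermate 2 and Experimental 6 (median -0.13, camera, adjusted p = 0.0143). The vitamin D median ran from -0.12 to 0.19 with each library left out. Stat4 stood at 0.54, Spp1 at -0.64, Klk7 at 0.27, the ATP-gated channel P2rx3 at 0.65 and Uchl1 at -0.19. Among type 17 and neutrophil-attracting factors (median -0.22, camera, adjusted p = 0.193), Csf3, which drives neutrophil production, was 4.86 ± 1.58 CPM (SD, n = 4) and 1.33 ± 0.82 CPM (SD, n = 6), with a log2 fold change of -1.82 (edgeR, adjusted p = 0.0860), and Il1f8 (IL-36 beta) stood at 0.24. Both passed when adjusted over the list alone. That list passed in 4 of 23 alternatives, among them those without Littermate 1 (camera, adjusted p = 0.0337) and without Experimental 6 (0.0183). Its median ran from -0.34 to 0.03 with each library left out.

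No keratinocyte list other than that of the hair follicle passed in the main test. Epidermal differentiation and barrier genes had a median of 0.08 (camera, adjusted p = 0.211), with Lor at -0.57, and activated keratinocyte genes a median of 0.09 (adjusted p = 0.144), with Sprr2h at 0.67 and Stfa1 at 0.40. Sprr2h was the only one of 19 that passed when adjusted over the list alone. Cell division genes had a median of 0.07 (adjusted p = 0.144), with Ccnb1 at 0.23 and Mcm5 at 0.14, and sebaceous gland genes 0.08 (adjusted p = 0.243), with Fasn at -0.76 and Mc5r at 0.34. With a library left out, camera called the barrier list without Experimental 6 (adjusted p = 0.0484), the activated keratinocyte list without Experimental 3 or 4 (0.0475 and 0.0417), cell division without Littermate 1 or Experimental 3 or 4 (0.0108, 0.0303 and 0.0279), and sebaceous gland without Littermate 3 or 4 (0.0198 and 0.0469). With no filter on low counts the barrier, activated keratinocyte and cell division lists passed (0.0361 for each). Hair follicle genes stood higher, with a median of 0.53 over 14 tested members (camera, adjusted p = 0.0066 with the preset correlation and 0.675 with an estimated correlation). None of them passed over all genes and S100a3, at 1.11, passed when adjusted over the list alone, while Krtap3-1 stood at 1.55. The list lost its call without Littermate 2 (adjusted p = 0.0678).

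Altogether 15 of the 40 lists passed with the preset correlation, none with an estimated correlation and none with fry in 1 direction, while 6 passed fry for changes in either direction. With each library left out in turn, 3 of the 15 kept their call in all 10 fits (mitochondrially encoded, immediate early and heat shock, and mast cell genes), and 12 of the other 25 lists gained one in at least 1 fit. Of these 3, the immediate early list lost its call without Littermate 2 and with GC correction (adjusted p = 0.183) and the mast cell list without the 2 deepest libraries (0.0641). The mitochondrially encoded list kept its call in every camera fit with the preset correlation. With the level of the Y-linked genes as a covariate, which stood higher on average in Experimental libraries, the basophil (adjusted p = 0.311), macrophage (0.0553), fibroblast (0.966), endothelial (0.977), melanocyte (0.173) and ribosomal protein (0.977) lists lost their call. The Y-linked list lost it by construction. In the same fit the lists of activated keratinocytes and cell division (0.0142 for both), dendritic cells (0.0303), T cells (0.0284), B and plasma cells (0.0009) and adipocytes (0.00069) passed. The list with the lowest p was the mitochondrially encoded genes. Its 7 tested members, of 13 in the files, all had negative log2 fold changes with a median of -0.67 (camera, adjusted p = 1.5e-08, and adjusted p = 0.480 with an estimated correlation). The others did not pass the filter on counts, for a reason not tested here, so the 7 may not stand for all 13. No member passed over all genes and 6 passed when adjusted over the list alone. mt-Nd5 stood at 575 ± 165 CPM (SD, n = 4) and 316 ± 36.9 CPM (SD, n = 6), a log2 fold change of -0.86, and mt-Cytb at -0.63 (edgeR, adjusted p = 0.0834 for both). Immediate early and heat shock genes had a median of -0.27 (camera, adjusted p = 0.00029, and adjusted p = 0.480 with an estimated correlation), with 4 of 14 passing when adjusted over the list alone, among them Jun at -0.24 and Fosb at -0.76. Ribosomal protein genes had a median of 0.08 (adjusted p = 0.0002, and adjusted p = 0.675 with an estimated correlation), with Rps27a at 0.48 and the kinase Rps6ka1 at -0.31. The ribosomal median was 0.03 without Littermate 4, where the call was lost (adjusted p = 0.0638), and 0.18 without Littermate 2. The replication-dependent histones had a median of -0.12 (adjusted p = 0.0240, and adjusted p = 0.718 with an estimated correlation), with Hist1h3c at -0.29 and Hist1h2be at -0.28. The histone call was lost without Littermate 1 (adjusted p = 0.479), Littermate 2 (0.975), Experimental 4 (0.117) or Experimental 6 (0.196), and with GC correction (0.825, median -0.01). The histone median was -0.03 without Littermate 1, -0.02 without Littermate 2 and -0.07 without Experimental 4.

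Among immune cells, the macrophage and monocyte list had a median of -0.17 over 16 members, of which only Lyz2 passed (camera, adjusted p = 0.0240, and adjusted p = 0.675 with an estimated correlation), while Ccr2 stood at 0.30. The macrophage call was lost without Littermate 1 (adjusted p = 0.0784), Littermate 2 (0.106), Experimental 4 (0.155) or Experimental 5 (0.0641). Mast cell genes had a median of -0.20 (adjusted p = 0.0169, and 0.675 with an estimated correlation), with the transcription factor Gata2 at -0.70 and the protease Mcpt4 at -0.21. Gata2 alone passed when adjusted over the list alone. Basophil genes had a median of -0.34 (adjusted p = 0.0460, and 0.675 with an estimated correlation), with Cd200r3 at -0.54 and Cyp11a1 at -0.29, and kept their call only without Littermate 3, Experimental 2 or Experimental 6 among the 10 fits with a library left out (adjusted p from 0.05 to 0.114 in the other 7). The basophil median was -0.58 without Experimental 6 and ran up to -0.24, without Experimental 3. Interferon response genes had a median of 0.28 (adjusted p = 0.0226, and 0.697 with an estimated correlation), with Irf1 at 0.35. The interferon call was lost without Littermate 2, 3 or 4 (adjusted p = 0.130, 0.218 and 0.0978) or Experimental 1, 3 or 6 (0.0574, 0.106 and 0.129), and the median ran from 0.03 to 0.57 over the alternatives. It was 0.57 without Littermate 1, 0.12 without Littermate 2, 0.08 without Littermate 3, 0.43 without Experimental 4 and 0.15 without Experimental 6. The lists of neutrophils (median -0.32, camera, adjusted p = 0.0550), eosinophils (0.00, adjusted p = 0.548), dendritic and Langerhans cells (0.07, adjusted p = 0.193), T cells (0.15, adjusted p = 0.211), B and plasma cells (0.42, adjusted p = 0.138) and NK and innate lymphoid cells (0.10, adjusted p = 0.243) did not pass. Without Experimental 6 the neutrophil list passed with a median of -0.49 (camera, adjusted p = 0.00021), and the dendritic list passed (0.0303). The neutrophil list, which passed in 8 of 23 alternatives, also passed without Littermate 1 (adjusted p = 0.0411), and the B and plasma cell list without Littermate 4 (0.0284, median 0.96). Ccr7, at 0.66, passed when adjusted over the dendritic list alone. Stfa2l1 stood at -1.0, Csf3r at -0.62, Ccr3 at 0.45, Alox15 at -0.22, Flt3 at 0.40, Cd4 at -0.43, Cd2 at 0.41, Jchain at 0.97, Cd79b at -0.42, Nkg7 at 0.33 and Il7r at 0.10. Jchain was 6.93 CPM in Littermate 4 against 0.147 to 1.42 CPM in the other Littermates. Its log2 fold change ran from 0.44 to 2.95 over the alternatives.

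Among other tissues of the ear, skeletal muscle genes had a median of -0.25 (camera, adjusted p = 0.0253, and adjusted p = 0.697 with an estimated correlation), with Tnnc2 at -1.48 and Myh1 at -0.47. Without Littermate 3 the muscle list lost its call and turned to a median of 0.03 (adjusted p = 0.862), and the call was also lost without Littermate 2 (0.50), Experimental 1 (0.05) or Experimental 2 (0.0520). The muscle median was -0.41 without Littermate 1, -0.16 without Littermate 2 and -0.39 without Littermate 4. Fibroblast and matrix genes had a median of -0.13 (adjusted p = 0.0226, and 0.675 with an estimated correlation), with Col5a1 at -0.49 and Eln at -0.48, and lost their call without Littermate 1 or 4 or Experimental 4 (adjusted p = 0.0940, 0.127 and 0.0943). The fibroblast median was -0.07 in each of these 3 fits, -0.22 without Littermate 2, and -0.21 without Littermate 3 or without Experimental 6. Endothelial genes had a median of -0.08 (adjusted p = 0.0240, and 0.675 with an estimated correlation), with the lymphatic genes Prox1 at -0.52 and Flt4 at -0.41. These and Tie1 passed when adjusted over the list alone, and the list lost its call without Littermate 4 or Experimental 3 or 4 (adjusted p = 0.171, 0.0739 and 0.0786). The endothelial median was -0.02 without Littermate 4, -0.05 without Experimental 4, -0.14 without Littermate 2 and -0.13 without Experimental 6. Melanocyte genes had a median of -0.34 (adjusted p = 0.0253, and 0.675 with an estimated correlation), with Tyr at -0.70 and Tyrp1 at -0.35, and lost their call without Littermate 2 or 4 (adjusted p = 0.472 and 0.0978), with a median of -0.16 in the first of these fits. Glucocorticoid response genes had a median of -0.20 (adjusted p = 0.0311, and 0.675 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at -0.35 and Zbtb16 at -0.59, and lost their call without Littermate 3 or 4 or Experimental 1 or 2 (adjusted p = 0.121, 0.127, 0.178 and 0.131), with a median of -0.09 without Littermate 4. The lists of cartilage (median -0.13, camera, adjusted p = 0.0810), adipocytes (-0.14, adjusted p = 0.893), red blood cells (-0.61, adjusted p = 0.0957), Schwann cells (-0.09, adjusted p = 0.465) and the circadian clock (-0.02, adjusted p = 0.605) did not pass. With a library left out, cartilage passed in 5 of 10 fits, without Littermate 3 or 4 or Experimental 2, 4 or 5 (adjusted p from 0.0018 to 0.0464), red blood cells without Littermate 1 or Experimental 3 (0.0126 and 0.0069), and adipocytes without Littermate 4 (0.0162, median 0.13). Over these 10 fits the cartilage median ran from -0.25 to 0.02 and that of red blood cells from -0.84 to -0.04. Col2a1 stood at -0.95, Pck1 at -0.79, Thrsp at -0.66, Hbb-bt at -0.61, Hba-a2 at -0.63, Pmp22 at -0.24, Cdh19 at 0.22, Npas2 at -0.75 and Nr1d1 at -0.54. Adjusted over the list alone, Npas2 and Nr1d1 passed in the clock list and Sox9 in the cartilage list. Tnnc2 did so in the skeletal muscle list and Cdkn1a in the glucocorticoid response list. The camera direction went against the sign of the median for adipocytes, itch mediators, sensory neurons and genes near Jak1. It went against the sign of the mean for adipocytes and for genes near Scn10a. All 10 libraries held Y-linked reads, at 226 to 337 CPM, and Xist reached at most 0.367 CPM. The Y-linked genes had a median of 0.18 (adjusted p = 0.0169, and 0.675 with an estimated correlation), with Kdm5d at 0.17 and Eif2s3y at 0.20, and lost their call without Littermate 4 (median 0.12, adjusted p = 0.0638).

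**Figure D2:**
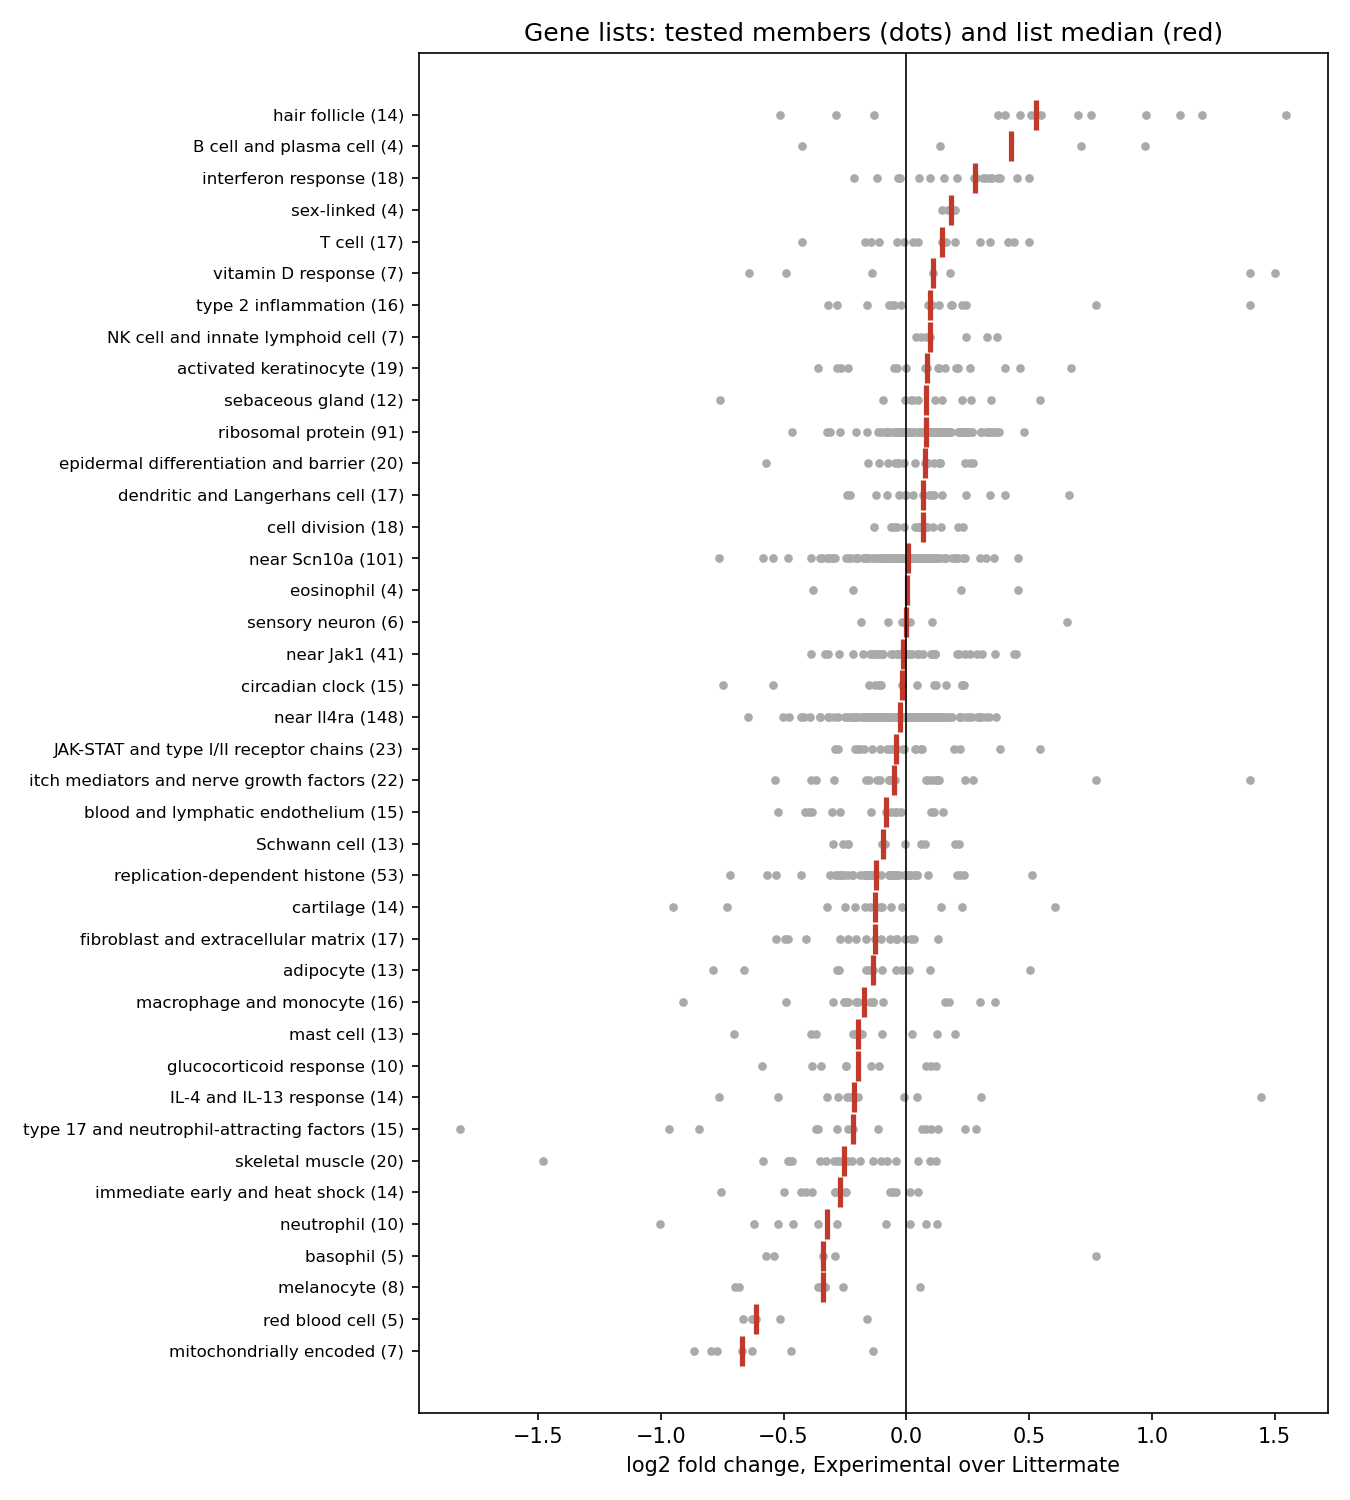
Log2 fold change, Experimental over Littermate (x axis), of the tested members of each of the 40 gene lists (grey dots, number of members in brackets), ordered by the list median (red marks). The mitochondrially encoded list has the lowest median, -0.67, and the hair follicle list the highest, 0.53.

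Some measures of library composition leaned with the groups, though none of those tested passed after adjustment. Log2 fold changes fell with the GC content of the transcript, across 16718 genes, from a median of 0.08 in the lowest decile to -0.13 in the highest decile (Spearman's rho = -0.35 across genes, which are not independent replicates). In single libraries the correlation of a gene's deviation with its GC content ran from -0.10 to 0.33 in Littermates and from -0.33 to 0.04 in Experimental libraries, and the difference in group means did not pass after adjustment over 7 library measures (exact permutation test, two-sided, adjusted p = 0.117). The mitochondrially encoded share of counts was 0.771% ± 0.0970 (SD, n = 4) in Littermates and 0.601% ± 0.0576 (SD, n = 6) in Experimental mice (exact permutation test, two-sided, p = 0.00952, adjusted p = 0.0667). This share also counts the ribosomal RNAs mt-Rnr1 and mt-Rnr2, in libraries depleted of ribosomal RNA. The totals, the share of the top 10 genes and the shares of haemoglobin, abundant noncoding RNA and muscle RNA had adjusted p from 0.353 to 0.433 in the same test. The first principal component held 24.5% of the variance, and the difference of the groups on it did not pass (exact permutation test, two-sided, p = 0.0571). The series text counts 6 mice and 4 littermates, so each library is taken as 1 animal.

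**Figure D3:**
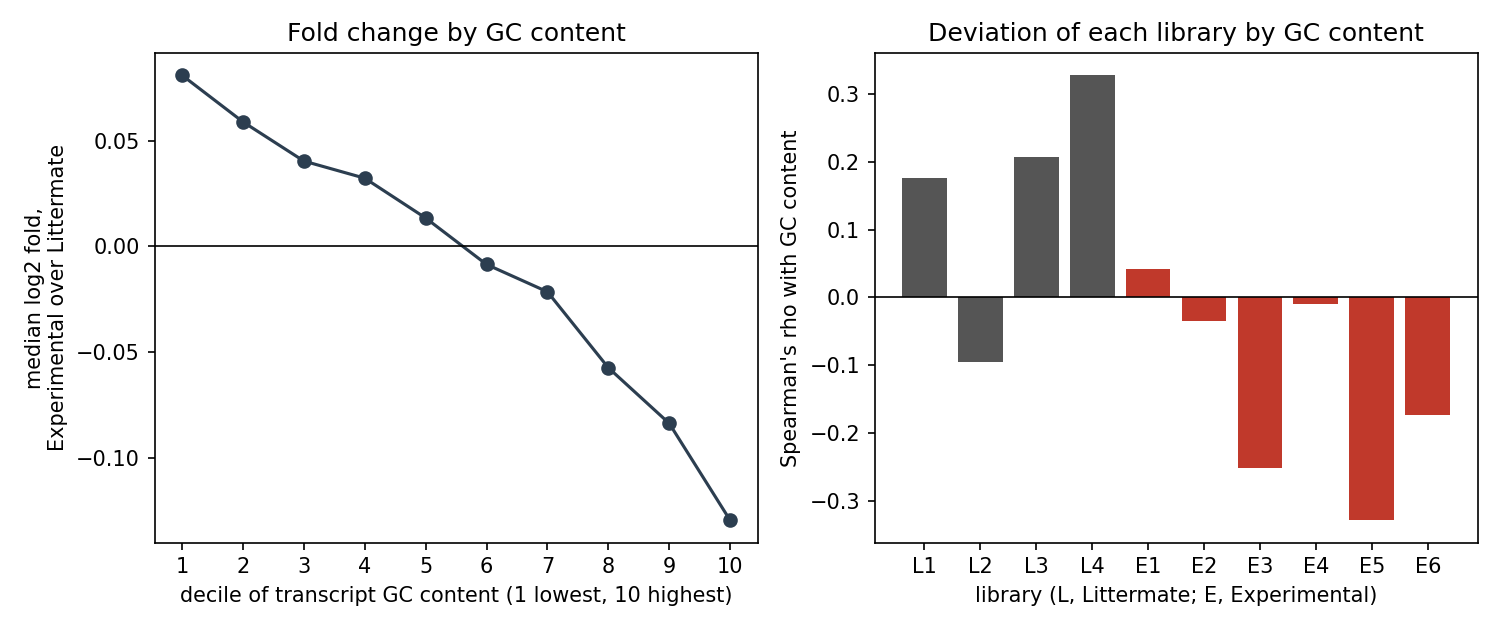
Left, median log2 fold change of Experimental over Littermate (y axis) in deciles of the tested genes by transcript GC content (x axis), which falls from 0.08 to -0.13. Right, Spearman's rho between each gene's deviation in a library and its GC content (y axis) for each library (x axis), with Littermates in grey and Experimental libraries in red.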

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

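In each group the highest or lowest library was set against the rest by its gap to the nearest other library, for named genes, gene list scores (mean deviation on the log2 scale) and measures of whole libraries. Chance flags about 1 in 20 groups, and 16 of 290 were found where 14.5 would be expected, so single cases carry little weight. The cases fell unevenly, with 7 in Experimental 6.

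Each library is compared here with the others of its own group only. Experimental 6 stood above the other Experimental libraries in 3 named immune genes and 3 immune cell lists. Its Stfa2l1 was 3.03 CPM against at most 1.05 in the others, its Csf3r, the receptor for G-CSF, 43.1 against at most 17.4 CPM, and its Il7r 24.2 against at most 20.1 CPM. Its list scores were 0.717 for neutrophils, 0.832 for basophils and 0.275 for mast cells, where the next libraries had -0.045, -0.094 and -0.12. Its Col5a1 was 271 CPM, where the next had 225 CPM.

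Within its group, Experimental 4 had the highest S100a3, at 7.76 CPM against at most 4.63, the highest Fosb, at 6.45 CPM against at most 3.59, and the highest immediate early and heat shock score, at 0.135, although Littermates reached 7.69 CPM of Fosb and a score of 0.223. Littermate 1 had the highest interferon response score of its group, 0.739 against at most -0.36, and the highest hair follicle score, 0.0735. Experimental 5 had the highest skeletal muscle score of its group, 0.30, where Littermate 3 had 0.690. Littermate 3 had the lowest Eln of its group, at 85.4 CPM, where the next had 127 CPM. The Scn10a values of 0.0733 CPM in Littermate 2 and 0.0270 CPM in Experimental 2 are 1 count each, under the floor of 3 counts.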

How the results depend on the processing

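Lyz1, Lyz2 and Sox9 kept their direction in all 24 alternative fits, with log2 fold changes from 1.83 to 2.07, from -0.99 to -0.82 and from -0.75 to -0.68. Lyz1 and Lyz2 passed in all of them and Sox9 in 23. The number of changed genes did not hold. It was 78 (7 higher, 71 lower) with no filter, 232 (36 and 196) with DESeq2, which made 12.9% false calls in the simulation, and 60 (4 and 56) with voom and quality weights. Leaving out each library in turn gave 3 to 343 genes (1 to 36 higher, 2 to 307 lower), with the highest count without Littermate 2. Chosen after seeing the data, the fit without Littermate 2 and Experimental 6 gave 563 (102 and 461), and that without Littermate 2 and with GC correction 54 (4 and 50), so part of the rise without Littermate 2 went with GC content. GC correction of all libraries gave 4 and added Cd209d. With the replicate number as a block 67 genes passed (11 and 56). For pairing, each gene's group mean was subtracted from its log2 CPM, and the remaining deviations were correlated between libraries of the 2 groups. Deviations of same-numbered libraries had correlations of 0.03, -0.02, 0.09 and -0.02, and only Littermate 3 correlated best with its own number. The highest such correlation with any partner was 0.139, so these values cannot exclude that the numbers pair animals. The cause of the rise to 67 was not tested. With the level of the Y-linked genes as a covariate 2 genes passed (1 and 1) and Sox9 did not. All 10 libraries held Y-linked reads, so this level does not separate the sexes here, and it stood higher on average in Experimental libraries, so the covariate takes up part of the group difference. It also takes up most of the GC trend, whose correlation was -0.352 in the main fit and -0.0697 with this covariate. Of 97 named genes 93 kept their sign in all fits, and 46 that did not pass in the main test passed in at least 1 alternative.

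Of the lists, 15 passed in the main test, 0 with an estimated correlation, 0 with fry, 9 without the 2 deepest libraries, 8 without Littermate 2 and with GC correction, and 9 to 18 with each library left out. Skeletal muscle turned to a median of 0.027 without Littermate 3, in a range from -0.408 with each library left out. Replication-dependent histones turned to 0.084 without Littermate 2 and with GC correction, and to 0.014 without Littermate 2 and Experimental 6. With the Y-linked level as a covariate 14 lists passed, while endothelial genes turned to 0.037 and ribosomal protein genes to -0.035. The causes were not tested. The first component held 20.9% and 26.9% of the variance under its alternatives. In the simulation edgeR missed a change of 1.5 times in about as many genes as it found. The adjustment accepts larger p-values where more genes are called, and the simulation gave 147 calls against 3 in the main test. In the main test Mmp13, at a log2 fold change of 1.26, did not pass (edgeR, adjusted p = 0.0895). The simulated rate therefore does not give the share of real changes missed here, which may be larger.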

Other observations

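On the first component, genes with high positive loadings included the keratin and keratin-associated genes Krtap13, Krt36 and Krt84, and those with negative loadings the transporter Slc15a2, which had the largest, the cytokines Cxcl2, Cxcl5, Ccl3, Csf3 and Tnfsf11, the transcription factor Pitx1 and the protease Prss34. These genes were chosen by their loadings after the values were seen, and no enrichment was tested. All 4 Littermates lay below 0 on it and 5 of 6 Experimental libraries above 0. Experimental 4 lay at 15.7, while Experimental 6 lay at -11.5, beyond all Littermates, which ran from -9.45 to -2.01. Littermate 2 stood apart on the second component, at -18.7, where no other library was below -4.87. Il4, also chosen after its values were seen, was 6.98 CPM in Experimental 6, 1.11 to 1.4 CPM in the other 5 Experimental libraries and 0.924 to 1.79 CPM in Littermates, and the group means did not differ (exact permutation test, two-sided, p = 0.743).

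All tests in the following paragraphs were chosen, or their criteria written, after the results were seen. Whether other splits of the 10 libraries give as much was counted over 100 of the 210 splits into 4 and 6, the real split included. Chance cannot be excluded for the count of 3 changed genes, which 5 of the 100 splits reached, with a highest other count of 6. It cannot be excluded for the 15 lists with the preset correlation, which 24 splits reached, with a highest other count of 22. For the 1978 genes at an unadjusted p under 0.05 the share was under 0.05, as 4 splits reached it, although the highest other count was 2279. Other splits can keep much of the real grouping. Littermates 1, 3 and 4 with Experimental 4 gave the 2279, and Littermates 2, 3 and 4 with Experimental 4 gave 6 changed genes. An even mix, Littermates 3 and 4 with Experimental 3 and 6, also gave 6. Such splits are no clean reference for chance, so these counts do not settle it in either direction. Complete separation of the groups was seen in 128 genes on the higher and 228 on the lower side, 2.12% of those tested, where chance gives 0.952% on average. Separated genes were not counted over the other splits and genes are not independent, so this excess does not exclude chance.

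Lyz1 stood higher and Lyz2 lower in every Experimental library. Reads passing from Lyz2 to Lyz1 as the whole cause would leave their sum unchanged if every read stayed counted. The sum fell from 464 ± 67.9 to 309 ± 22.3 CPM, a log2 ratio of -0.577 with a 95% interval from -0.803 to -0.351. The treatment of reads that match several places is not given. Reads dropped from both genes would lower the sum too, so the fall does not exclude misassigned reads. Fewer macrophages would lower the other markers alike, but the other 15 had a median of -0.148 with an SD of 0.238. Another Lyz allele in the Experimental mice, read differently by the aligner, may account for both changes and cannot be told apart from a difference in expression, since 0 of 17 neighbours within 1 Mb passed over that region and the counts hold no sequence. The genotype itself stays open, untested.

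GC-rich genes were lower in Experimental libraries. A GC bias of single libraries is a candidate explanation: 7 of the 100 splits gave a correlation at least as large as the real 0.352, and the highest other was 0.462. The 2 deepest libraries do not account for it, since the correlation was -0.352 without them. With the level of the Y-linked genes as a covariate the correlation was -0.0697. Across libraries that level tended to rise as the GC correlation fell. It was 226 CPM at 0.33 in Littermate 4 and 337 CPM at -0.33 in Experimental 5. Kdm5d and Eif2s3y are themselves GC-poor, at 43.8% and 36.4%. The covariate is therefore no separate test of the trend. A biological explanation was not tested apart from the groups.

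Mitochondrially encoded RNA was lower on average in Experimental libraries. The list did not pass with an estimated correlation (camera, adjusted p = 0.480), nor did the share of counts (exact permutation test, two-sided, adjusted p = 0.0667). The list score of Littermate 2, -0.069, lay within the Experimental range of -0.476 to -0.024. The GC trend argues the other way, since the list median was -0.786 after GC correction against -0.67 before. Less skeletal muscle is also argued against, since the group difference in the log2 share was -0.365 with an SE of 0.112 with muscle share as a covariate and -0.355 without. Differences in RNA handling or tissue state stay open, and no test here separates them from the genotype.

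A hypothesis for Tslp, at a log2 fold change of 1.4 with 6 of 6 Experimental libraries above all Littermates, is that the Experimental skin may have responded more to the vitamin D analogue. Cyp24a1, the most direct vitamin D target, was chosen for the test after its values were seen. Its log2 fold change was 0.179 with an interval from -0.120 to 0.478, which lies below that of Tslp. This is 1 of 7 tested genes of the vitamin D list. Of the others S100g, also picked after its values were seen, stood at 1.5 with an interval from 0.118 to 2.885 (edgeR, adjusted p = 0.385), and Spp1 at -0.64, so the list does not settle the hypothesis and it stays open. Tslp did not pass over all genes in the main test and passed in 3 of 24 alternatives: DESeq2, voom with quality weights, and edgeR without Littermate 2 and Experimental 6. Its adjusted p ran from 0.0257 to 0.827 over the alternatives (edgeR, limma or DESeq2).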
